A study of Mus musculus with 12 samples.

How the data were processed

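The study measured poly(A) RNA of mouse embryonic fibroblasts (MEF) and of cells reprogrammed from fibroblasts by the Sendai virus vector SeVdp(fKOSMaB). Some courses received 30 nM Shield1, a small-molecule ligand that stabilises proteins fused to a destabilising domain. Per the labels' protocols, RNA was taken with ISOGEN, 500 ng of total RNA per library went through poly(A) selection and a directional NEBNext kit, and paired reads of 76 bases were sequenced on a NextSeq500. The labels name 12 libraries: MEF1 and MEF2 at day 0, LowK without Shield1 at days 35, 52 and 56, MidK1 with 30 nM Shield1 at the same days, and MidK2 with 30 nM Shield1 at days 18, 22, 29 and 36. Each reprogrammed library is 1 library per course and day, so the group tests below take days of a course as their units and do not measure the spread between cultures. The mouse strains, the parental origin of each X chromosome, the use of feeder cells and whether MEF1 and MEF2 were separate cultures are not given in the sources used here.

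Each library had a table of variants on the X chromosome against the mouse reference genome, called by the authors with the Basic Variant Call tool of CLC Genomics Workbench (per the series description) on build mm10 (per the submitters' processing notes). The aligner, the read filters and the caller's settings are not given in the sources used here. Per the file headers, each variant has the count of reads with the variant allele and the count of reads covering the position, neither of them normalised. Per the file headers, each variant also has the percent of covering reads with the variant allele, which equalled 100 times count over coverage to within 5.04e-09 percentage points. The average base quality, a score given per the file headers in 7 of the 12 tables, was used only as a filter in an alternative setting. The values show that 2 sets of tables were made with different limits. In the set of MEF1, LowK and MidK1 (7 libraries) the lowest variant count was 5 and the lowest variant percent was at or just above 10. In the set of MEF2 and MidK2 (5 libraries) the lowest count was 2 and the lowest percent was 5, and the lowest coverage was 10 in both sets. These sets were treated as batches, and each reprogrammed library was compared first with the MEF library of its own set. A position at which all reads carry the reference allele is not listed, so it counted as missing, and the reference share of a listed site cannot exceed about 90% in the first set and 95% in the second. A site where both X chromosomes carry the variant stays almost all variant, whichever chromosome is active. Such sites cannot be told apart here and count among those not biallelic.

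Sites were single-nucleotide variants covered by at least 20 reads. Where a position listed more than 1 variant allele, the one with more reads was kept, which dropped 54 second alleles. Sites took the gene name given in the tables. Of 13485 variant positions, 12291 had a gene name, 789 had several, and 447 of those were given to the single gene with an exon there in the GENCODE M21 annotation of the same build. The 6478 different sites with at least 20 reads in some library included 2354 in coding sequence, 3071 in untranslated regions, 193 in exons of noncoding transcripts and 254 in introns. A site was called biallelic at a variant share of 10 to 90%, and a gene at a median minor share over its sites of at least 10%, where the minor share is the smaller of the shares of the variant and of all other reads. A position all reference in MEF is not listed there and appears in another library only once its variant share reaches the caller's limit. In the first set that limit is also the lower bound for a biallelic site. Such newly listed sites can thus raise biallelic shares by themselves. The reference share of a gene is the percentage of reads over its sites that did not carry the variant allele. The design had called for sites to be oriented to 1 allele class, but they were not. A gene can therefore sum almost all-variant with almost all-reference sites, as Fundc1 did in MEF2 (44.7% over 5 sites, median minor share 0). Shares of 1 library have 95% Wilson intervals. Reads carry no molecular identifiers and several sites of a gene can lie on 1 read, so intervals and tests on reads cover counting error only. At a site with the median coverage of 35 to 39 reads per library, minor shares near 10% rest on few reads, so single sites were not interpreted.

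Pairs of libraries were compared at sites listed in both. Per gene, variant and other reads were summed over the shared sites and compared with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the genes of a pair. A gene was called changed at an adjusted p under 0.05 and a difference of at least 20 percentage points in reference share. Per pair, an exact McNemar test compared the genes biallelic in 1 library alone, with Benjamini-Hochberg adjustment over 32 pairs. Both tests compare 2 libraries, not 2 conditions. Shares of biallelic genes per library were compared between groups with two-sided exact permutation tests, and LowK with MidK1 by sign flips over days. Clustering of changed genes along the chromosome was tested on their mean position with all circular shifts of the calls over the tested genes and with a permutation test of 100000 resamples. The design had named 100000 circular shifts, but a pair has no more different shifts than tested genes. Biallelic genes of 5 lists (escape from X inactivation, X-inactivation centre, housekeeping, pluripotency and germline, fibroblast-expressed) were compared with all other measured genes by Fisher's exact test, with Benjamini-Hochberg adjustment over 60 tests. Bgn and Xist are in 2 lists each.

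The lists, tests, thresholds and the rule for named genes were set before the data were examined. Named are the list members measured in both libraries of a comparison, the 10 called genes with the largest change per main comparison at a coverage of at least 100 reads in both libraries, and the 5 genes of highest coverage among those biallelic in both MEF libraries and among those not biallelic in the last library of each course. Any other gene is named as chosen after its values were seen. The boundary at 30 Mb, the marker sites (a variant share of at least 90% in an MEF library) and the use of the median minor share rather than the summed share as the main gene measure were set after seeing the data; the summed share is among the alternatives.

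Alternatives were coverage minimums of 10 and 50 reads, a biallelic window of 20 to 80%, all variant types, a base quality of 30 with reads on both strands, sites thinned to 20 reads, a single site per gene, no minimum difference, windows of 5 Mb instead of 10 Mb, the stricter caller limits in all libraries, and leaving out libraries, days, regions or lists. A further alternative left out sites with a variant share over 90% in every library that measured them. The gene test was tested on simulated data for MEF1 against MidK1 day 56 (156 genes, 20 draws, 15 genes per size of change). With independent reads it called 8.33% of genes changed by 15 points, 95.3% of those changed by 30 and 99.7% of those changed by 50, and 0.045% of unchanged genes. With extra spread between libraries it called 23.0%, 89.7% and 99.7%, and 0.811% of unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.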

Results

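Allele-specific transcription from the X chromosome was measured in 12 libraries, 2 of fibroblasts and 10 of cells under reprogramming. Female fibroblasts keep 1 X chromosome silent, and reads of the silent copy reappear when it is reactivated, so the design asks how far, when and where both alleles are read during reprogramming, and whether Shield1 changes this. The tables listed 3245 to 7991 variants per library, of which 1507 to 3871 were single-nucleotide sites with at least 20 reads, in 193 to 340 genes. Total coverage over those sites was 138579 to 279031 reads per library. MEF libraries had 1507 and 1981 sites and reprogrammed libraries 2188 to 3871. There were no biological replicates of any reprogrammed time point.

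In fibroblasts most measured genes were read mainly from the variant allele, and a small group was read from both. Only positions with variant reads are listed, so genes read from the reference allele alone are not seen here. The median variant share per site was 96.2% in MEF1 and 99.3% in MEF2. Of 180 genes measured in both MEF libraries, 9 were biallelic in both. The 5 of these with the highest coverage were Ddx3x, an RNA helicase (X:13280970-13294052, mm10), with reference shares of 42.8% (95% interval 40.5 to 45.2) in MEF1 and 44.5% (42.0 to 47.1) in MEF2, Kdm5c, a histone demethylase, Eif2s3x, a translation initiation factor subunit, Pbdc1 and the ribosome biogenesis gene Utp14a. All 5 are on the list of genes that escape X inactivation. Of that list, 6 of 10 measured members were biallelic in MEF1 and 6 of 11 in MEF2, against 8.74% and 2.48% of the other genes (Fisher's exact test with Benjamini-Hochberg adjustment over 60 tests, adjusted p = 0.00106 and 3.18e-05). Xist, the noncoding RNA that coats the silent X chromosome (X:103460366-103483254), went the other way. In MEF2 80.7% (75.4 to 85.1) of its 254 reads carried the reference allele, and in MEF1 it had 1 site with 23 reads, all of the variant allele, which is too little for a comparison.

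The MEF libraries themselves differed slightly. Of measured genes, 22 of 193 were biallelic in MEF1 (11.4%, 7.65 to 16.7) and 11 of 213 in MEF2 (5.16%, 2.91 to 9.01). Over all sites of each library, 9 genes were biallelic in MEF1 alone and 1 in MEF2 alone. At shared sites these numbers were 9 and 0 (exact McNemar test, adjusted p = 0.00521 by Benjamini-Hochberg). No gene of 174 was called changed between them by Fisher's exact test, while 53 had an adjusted p under 0.05 at any size of difference. MEF1 and MEF2 belong to tables with different caller limits, but such limits do not set the allele share at sites listed in both. Over the 174 genes the median difference in reference share, MEF2 minus MEF1, was -1.70 points. At the marker sites each library measured, 3.61% of reads in MEF1 and 1.07% in MEF2 were of the reference allele. The cause was not tested.

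Without Shield1, reference reads appeared late and at few genes. In LowK at day 56, Timp1, an inhibitor of matrix metalloproteinases (X:20870166-20874735), had a reference share of 44.1% (35.3 to 53.4) against 2.93% (1.86 to 4.59) in MEF1. Dynlt3, a dynein light chain gene (X:9654267-9663003, 29 of its 30 sites in untranslated regions), had 36.1% (33.3 to 38.9) against 5.99% (4.74 to 7.55), and Hdac6, a cytoplasmic deacetylase gene (X:7930120-7947889), had 29.8% (27.2 to 32.5) against 2.41% (1.49 to 3.88). The uncharacterised escape-list gene 1810030O07Rik reached 46.7% (37.4 to 56.2), and the mitophagy receptor gene Fundc1, Wdr13 and the thioesterase gene Acot9 were also called, at 23.7 to 28.7%. The call of Wdr13 was lost with at least 10 reads per site (18.1 points) and at the single site with the highest coverage (18.8 points), and that of Fundc1 at the single site (22.4 points, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0787). The call of Hdac6 was lost with at least 50 reads (19.6 points). The count of called genes against MEF1 was 2 of 163 at day 35, 3 of 170 at day 52 and 8 of 163 at day 56, none of them lower (Fisher's exact test, adjusted p under 0.05 by Benjamini-Hochberg and at least 20 points). Those of day 35 were Bgn and Tceal3, and those of day 52 were 1810030O07Rik, Fundc1 and Tceal3, where Tceal3 (1 site) was chosen after its values were seen. A fall of 20 points was out of reach for most genes, so the lack of lower calls carries little weight. The genes tested at day 56 had median MEF1 reference shares of 3.52% in the first 30 Mb and 3.87% outside it. The share of biallelic genes was 7.95% (5.26 to 11.9) at day 35, 14.7% (11.1 to 19.3) at day 52 and 22.1% (17.7 to 27.4) at day 56. With a coverage minimum of 50 reads, 1 gene of 66 was called at day 56.

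With Shield1, MidK1 cells had reference reads at more genes. At day 56 Dynlt3 stood at 61.1% (58.8 to 63.4), Tfe3, a transcription factor gene linked to the pluripotent state (X:7762560-7775202), at 53.3% (51.2 to 55.5) against 2.46% in MEF1, and Uba1, the gene of the main ubiquitin-activating enzyme (X:20658326-20683179), at 47.0% (45.0 to 49.0) against 4.56% (3.78 to 5.49). Hdac6 rose from 2.49% to 38.9% (36.3 to 41.7) and Timp1 from 3.32% (2.27 to 4.81) to 47.8% (43.6 to 52.1). Called genes against MEF1 were 13 of 153 at day 35, 20 of 155 at day 52 and 22 of 156 at day 56, and all had a higher reference share. Here too most genes started too low in MEF1 to be called lower. Biallelic genes made up 23.2% (18.5 to 28.7), 28.1% and 38.9% (33.3 to 44.8) on those days. Genes of high coverage that were not called at day 56 included Rlim, a ubiquitin ligase gene whose product activates Xist, at 2.59% against 4.30% in MEF1, Pdha1 of pyruvate dehydrogenase, at 6.69% against 3.51%, the chromatin remodeller gene Atrx, at 9.41% against 7.38%, and the ribosomal protein gene Rps4x, at 9.03% against 2.35%. Gm14681 had 0.603% (0.477 to 0.761), but it is a processed pseudogene whose reads can be shared with near-identical copies, so its value is uncertain. A low reference share does not show a silent allele where both X chromosomes may carry the variant. With a coverage minimum of 50 reads, 9 genes of 64 were called at day 56.

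Bgn, which encodes the matrix proteoglycan biglycan (X:73483602-73495933), had the highest reference share among the called genes with at least 2 sites at MidK1 day 56. It went from 3.64% (3.43 to 3.87) of 28206 reads in MEF1 to 80.6% (77.7 to 83.2) of 809 reads, and in MidK2 from 1.21% (1.09 to 1.34) of 30319 reads in MEF2 to 80.4% (75.4 to 84.6) of 281 reads at day 36. Bgn is also on the list of fibroblast-expressed genes, and its coverage in reprogrammed libraries was far below that in MEF. Plp2, at 87.5% (83.0 to 91.0) in MidK1 day 56, was measured at 1 shared site. Fully reference sites are not listed, so shares near 90% are close to the highest that can be seen.

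In MidK2, which was sampled earlier, biallelic genes were most frequent in the middle of the course. They made up 11.6% (8.51 to 15.5) at day 18, 34.9% (29.9 to 40.3) at day 22, 31.2% (26.3 to 36.5) at day 29 and 17.4% (13.7 to 21.7) at day 36. Against MEF2, 4 genes of 189 were called higher and 1 lower at day 18, and 18 of 187, 18 of 181 and 20 of 192 were called higher on the later days with none lower. The genes of day 18 were 1810030O07Rik, Bgn, Dynlt3 and, chosen after their values were seen, Tceal3 and the lower Tmem29. Most genes started too low in MEF2 to be called lower. Those tested at day 36 had median MEF2 reference shares of 1.19% in the first 30 Mb and 1.1% outside it. At day 36 Dynlt3 stood at 55.0% (53.0 to 57.0) against 5.87% (4.81 to 7.13), Tfe3 at 33.6% (32.2 to 35.1) against 3.39% (2.43 to 4.69) and Uba1 at 22.5% (21.3 to 23.8) against 1.38% (1.02 to 1.85). The actin-binding genes Msn and Tmsb4x were called at day 22, Msn at 26.8% (25.3 to 28.4) against 1.01% (0.819 to 1.24) in MEF2. Beside this, fibroblast-expressed genes carried reference reads equal to 6.05% and 5.49% of their MEF2 coverage at days 22 and 29 (median over 14 list members), against 1.81% at day 18 and 0.952% at day 36. With a coverage minimum of 50 reads, 10 genes of 96 were called at day 36.

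**Figure D1:**
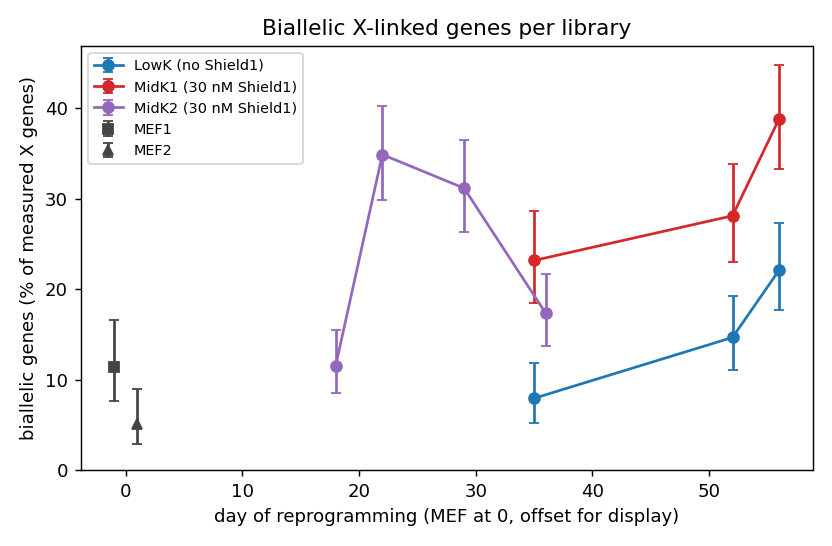
Share of measured X-linked genes that were biallelic (%) against day of reprogramming, with 95% Wilson intervals that cover counting error only; each point is 1 library and lines join libraries of a course. MidK1 lies above LowK on days 35, 52 and 56, and MidK2 runs from 11.6% at day 18 over 34.9% at day 22 to 17.4% at day 36. Sites not listed in MEF can raise the shares of reprogrammed libraries.

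Taken as groups, reprogrammed libraries had a higher mean share of biallelic genes than MEF libraries, but the ranges overlapped, with LowK day 35 below MEF1, and p was above 0.05. Sites listed only in reprogrammed libraries can add to this difference. The mean share was 8.28% ± 4.41 (SD, n = 2) in MEF and 14.7 points higher, ± 10.3 (SD, n = 10), in reprogrammed libraries (exact permutation test, two-sided, 66 splits, p = 0.0909; the smallest possible p is 0.0152). It was 5.83 points with a biallelic window of 20 to 80% and 9.18 points without the first 30 Mb (exact permutation p = 0.197 and 0.212). Within the set of MEF1 the difference was 11.1 points (exact permutation p = 0.429, 7 splits) and within the set of MEF2 18.6 points (p = 0.2, the smallest that 5 splits of an exact permutation test allow). By course it was 6.65 points for LowK, 21.8 for MidK1 and 15.5 for MidK2, with exact permutation p = 0.4, 0.1 and 0.133, where 0.1, 0.1 and 0.0667 are the smallest possible. Library by library, exact McNemar tests on shared genes against the MEF library of the same set gave an adjusted p under 0.05 (Benjamini-Hochberg) in 8 of 10 pairs, all but LowK days 35 and 52 (adjusted p = 0.600 and 0.0701). Pairs across the sets are not counted here, since MEF1 and MEF2 themselves differed by this test. Among those pairs only MidK2 day 18 and MEF1 were not parted. There 9 genes were biallelic in MidK2 day 18 alone and 7 in MEF1 alone (exact McNemar test, adjusted p = 0.804 by Benjamini-Hochberg). Genes biallelic in 1 library alone were 55 in MidK1 day 56 and 3 in MEF1 (exact McNemar test, adjusted p = 1.21e-12 by Benjamini-Hochberg).

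Of 150 genes tested in all 3 courses, 8 had a higher reference share in the last library of each: 1810030O07Rik, Acot9, Dynlt3, Fundc1, Hdac6, Tceal3, Timp1 and Wdr13. Tceal3 falls outside the rule for named genes and was taken up after its values were seen. LowK day 56 and MidK1 day 56 shared 8 higher genes, where independent lists would share 1.10, and both were compared with MEF1. In 100 simulated draws of unchanged libraries against MEF1, no gene was called in both. The draws kept the MEF1 counts as measured, so they cannot gauge an overlap that comes from its own error. MEF1 is 1 library and cannot be split, so part of the overlap can come from its own deviation. LowK day 56 and MidK2 day 36 shared 8 (0.866 for independent lists) and MidK1 day 56 and MidK2 day 36 shared 15 (2.59 for independent lists), each with its own MEF library.

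**Figure D2:**
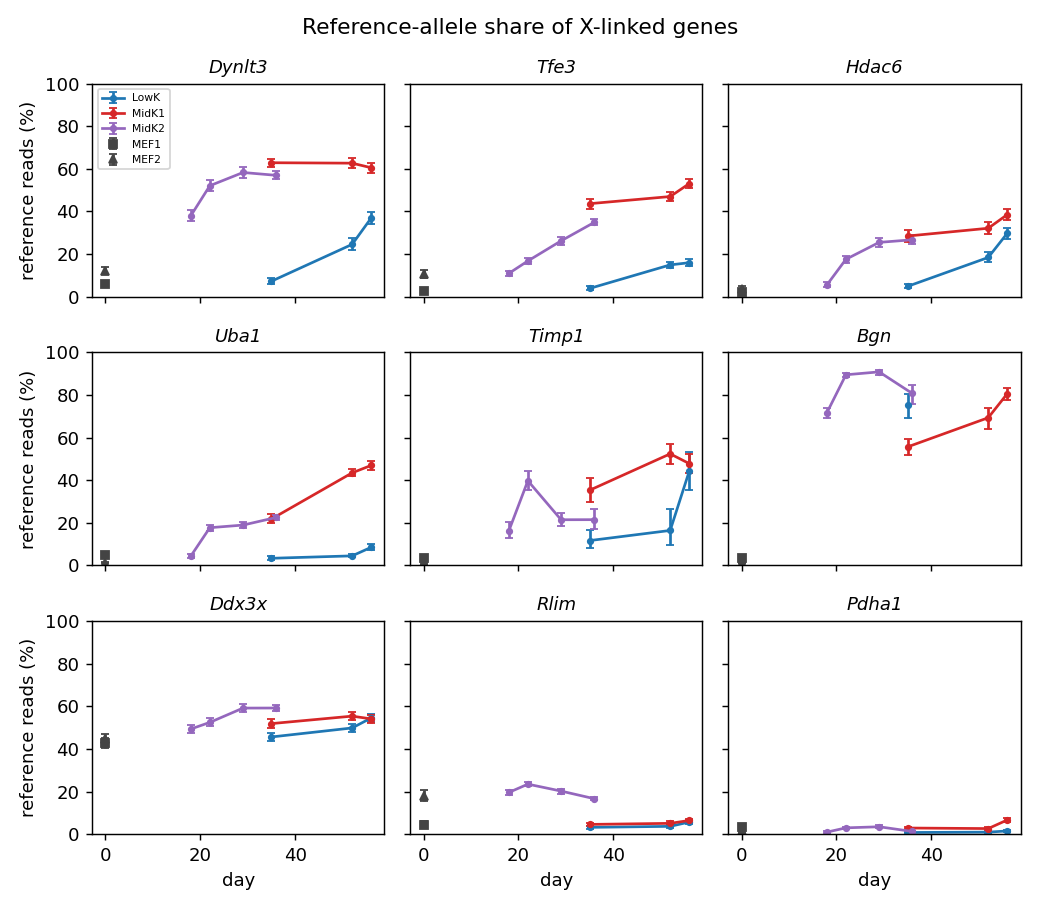
Reference-allele share (% of reads over all sites of the gene in a library, with 95% Wilson intervals) against day for 9 genes; squares and triangles are MEF1 and MEF2, and lines join libraries of a course. Dynlt3, Tfe3, Hdac6, Uba1 and Timp1 start near the bottom in MEF and lie higher in reprogrammed libraries, Ddx3x lies near the middle throughout, and Pdha1 stays low; Rlim lies higher in MEF2 and MidK2 than in the other set of tables, a difference whose cause was not tested.

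Among the fixed gene lists, escape-list genes were biallelic more often than other genes in all 12 libraries (Fisher's exact test, Benjamini-Hochberg adjusted p from 2.00e-07 in LowK day 35 to 0.0243 in MidK2 day 29), for example 11 of 12 members against 36.4% of other genes in MidK1 day 56. The other 4 lists gave no adjusted p under 0.05 in any library. Against MEF1, MidK1 day 56 had calls in 2 of 8 escape genes (1810030O07Rik and Bgn), 2 of 19 housekeeping genes (Uba1 and Atp6ap2, a proton pump accessory gene), 1 of 1 pluripotency and germline gene (Tfe3), 4 of 12 fibroblast-expressed genes (Timp1, Bgn, Plp2 and Lamp2) and 0 of 1 gene of the X-inactivation centre, and the counts adjusted over the list alone were the same 2, 2, 1, 4 and 0. Against MEF2, MidK2 day 36 had calls in 2 of 9 escape genes, 1 of 22 housekeeping genes (Uba1), 1 of 3 pluripotency and germline genes (Tfe3), 4 of 14 fibroblast-expressed genes and 0 of 2 genes of the X-inactivation centre, and adjusted over the list alone these were again 2, 1, 1, 4 and 0. In LowK day 56 they were 1 of 6 escape genes (1810030O07Rik), 1 of 13 fibroblast-expressed genes (Timp1), and 0 of 19, 0 of 2 and 0 of 1 in the other lists, with 1, 1, 0, 0 and 0 adjusted over the list alone. Ubiquitously used genes such as Hprt, Huwe1 and G6pdx did not pass the size limit in any of these 3 libraries.

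MidK1 libraries had clearly higher reference shares than LowK libraries at a minority of genes on each of the 3 matched days. Over all tested genes the median difference, MidK1 minus LowK, was 2.00, 1.92 and 2.90 points at days 35, 52 and 56. At day 35 Bcor, a transcriptional corepressor gene (X:12036740-12160355), had 56.5% (54.4 to 58.5) in MidK1 against 2.79% (2.07 to 3.75) in LowK, and Dynlt3 had 63.2% (61.2 to 65.2) against 5.30% (4.15 to 6.75). Over all libraries, 53 of the 91 sites of Bcor lay in introns. At day 56 Uba1 had 47.0% (45.0 to 49.0) against 8.54% (7.31 to 9.97), Bcor 54.5% (52.3 to 56.6) against 14.1% (12.4 to 16.0), the ubiquitin ligase adaptor gene Klhl13 (X:23219271-23365082) 54.4% (47.5 to 61.0) against 4.17% (2.28 to 7.50), Rbmx2 53.4% (48.2 to 58.6) against 12.3% (8.51 to 17.4), and Tfe3 53.4% (51.2 to 55.5) against 16.0% (14.3 to 17.8). The septin gene Sept6 and the escape gene Utp14a were called at day 56 too, at 31.2% against 2.49% and 48.6% against 23.8%. Timp1 and Tmsb4x did not differ at that day by the same test. Bgn was the exception at day 35, with 55.2% (51.1 to 59.3) in MidK1 against 75.2% (69.1 to 80.5) in LowK.

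MidK1 was called higher at 17 of 235 genes at day 35, with Bgn lower, at 21 of 244 at day 52 and at 21 of 243 at day 56 (Fisher's exact test with Benjamini-Hochberg adjustment). On the lists, higher genes were 2 of 9, 1 of 9 and 1 of 10 escape genes, 0, 1 and 1 of 25 housekeeping genes, 1 of 6, 1 of 7 and 1 of 6 pluripotency and germline genes (Tfe3 each time), 2 of 16, 3 of 14 and 1 of 14 fibroblast-expressed genes, and 0 of 2, 0 of 2 and 0 of 3 genes of the X-inactivation centre; each count was the same when adjusted over the list alone. Bgn, lower at day 35, adds 1 called gene to the escape and the fibroblast-expressed list on that day. The share of biallelic genes was higher in MidK1 by 15.2, 13.5 and 16.7 points, 15.1 ± 1.65 (SD, n = 3 days), in 3 of 3 days. An exact sign-flip test over 3 days gave p = 0.25 and an exact permutation test without pairing gave p = 0.1, both the smallest these designs allow. Between the 2 libraries of each day, 35, 36 and 46 genes were biallelic in MidK1 alone and 0, 2 and 7 in LowK alone (exact McNemar test, adjusted p = 1.86e-10, 1.33e-08 and 8.54e-08 by Benjamini-Hochberg). With a coverage minimum of 50 reads, 7 of 115, 8 of 117 and 12 of 123 genes were called.

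Both courses with Shield1 could be compared at days 35 and 36. Of 246 genes, 3 had a higher reference share in MidK2 day 36 and 3 in MidK1 day 35 (Fisher's exact test with Benjamini-Hochberg adjustment). Bgn was higher in MidK2, at 80.5% against 55.8%, and so were the Mediator gene Med14, at 54.8% against 16.1%, and the histone demethylase gene Phf8, at 60.2% against 37.8%. Higher in MidK1 were the histone demethylase gene Kdm6a, at 72.4% against 49.3%, Wdr13, at 47.2% against 25.1%, and Tceal3 (1 site), at 83.9% against 45.7%. Med14, Phf8 and Tceal3 were chosen after their values were seen. Biallelic status was lost at 14 genes and gained at 8 (exact McNemar test, adjusted p = 0.305 by Benjamini-Hochberg), and the 2 libraries belong to tables with different caller limits.

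Along the time courses, LowK and MidK1 gained biallelic genes from each day to the next, and MidK2 gained and then lost them. In MidK1, Uba1 rose from 21.8% to 43.8% and Rbmx2 from 23.9% to 49.0% between days 35 and 52, and Klhl13, Praf2, Enox2 and, chosen after its values were seen, Wdr45 (1 site) were also called. In MidK2 between days 29 and 36 Msn fell from 36.1% to 11.1%, Maged2 (1 site) from 54.5% to 3.85% and, chosen after its values were seen, the chloride channel gene Clcn5 from 27.3% to 3.36%, while Plp2 rose from 41.0% to 68.9%. In LowK, Fundc1 rose from 9.09% to 33.6% and Plp2 and Porcn were called between days 35 and 52, and Timp1 rose from 16.4% to 44.1% between days 52 and 56. Timm17b rose in the last step of MidK1, and Plp2 rose and Zfp275 fell between days 22 and 29 in MidK2, where Porcn, Timm17b and Zfp275 were chosen after their values were seen. Of 287 genes, 6 were called higher and 1 lower between days 18 and 22 in MidK2, and they are not named here. Between days 29 and 36 of MidK2, 42 genes lost and 5 gained biallelic status (exact McNemar test, adjusted p = 5.62e-08 by Benjamini-Hochberg), and between its days 18 and 22, 80 genes gained and 1 lost it (adjusted p = 1.09e-21). The other steps were 17 gained and 1 lost and then 18 and 0 in LowK, 20 and 5 and then 33 and 3 in MidK1, and 22 gained and 39 lost between days 22 and 29 in MidK2, each with an adjusted p under 0.05. Each step compares 2 libraries.

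Genes near the centromeric end of the chromosome had reference reads more often than the others, though many biallelic genes lay elsewhere. Dynlt3, Tfe3, Hdac6, Uba1, Timp1, Fundc1, Wdr13 and Bcor all lie in the first 30 Mb of mm10, as did 17 of the 22 genes called at MidK1 day 56, out of 32 tested there. In the first 10 Mb, 93.2% (89.3 to 95.8) of 237 sites were biallelic at MidK1 day 56 against 42.7% in the rest, 66.7% (59.8 to 72.9) against 21.8% at LowK day 56 and 71.3% against 20.4% at MidK2 day 36, while MEF1 had 12.3% against 15.1% and MEF2 3.47% against 10.3%. Sites not listed in MEF can add to the shares of the reprogrammed libraries. Genes in the first 30 Mb were biallelic more often than the others in 9 of 10 reprogrammed libraries (Fisher's exact test with Benjamini-Hochberg adjustment), for example 40 of 56 against 65 of 214 at MidK1 day 56 (adjusted p = 1.35e-07) and 28 of 56 against 31 of 284 at MidK2 day 36 (adjusted p = 2.31e-09). The boundary was set after these data were seen and neighbouring genes are not independent, so these p-values overstate the difference. LowK day 35 (adjusted p = 0.282), MEF1 (0.771) and MEF2 (0.756) had no such difference by the same Fisher's exact test. In a permutation test by circular shifts, which keep neighbouring genes together, the mean position of called genes gave p = 0.0131, 0.0129 and 0.00641 in the 3 MidK1 libraries, p = 0.0608 in MidK2 day 29, 0.25 in MidK2 day 36 and 0.252 in LowK day 56; with genes permuted singly these were 2.00e-05, 1.00e-05, 1.00e-05, 7.10e-04, 1.60e-04 and 0.0224, where 1.00e-05 is the smallest that 100000 resamples can give. In LowK day 52 and MidK2 days 18 and 22 the circular shifts gave permutation p = 0.453, 0.196 and 0.321 and single permutation gave 0.304, 0.287 and 0.313, with 6 of the 18 called genes of MidK2 day 22 in the first 30 Mb. Both tests thus gave p under 0.05 in the MidK1 libraries alone.

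**Figure D3:**
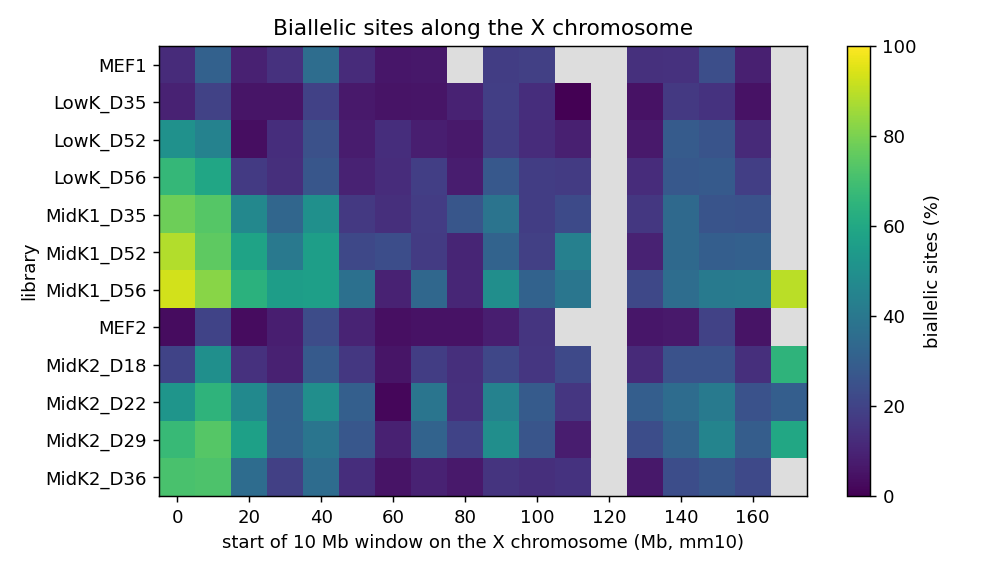
Share of biallelic sites (%, colour) in 10 Mb windows along the X chromosome (Mb, mm10) for the 12 libraries. Grey windows had fewer than 20 sites or none. The window of the first 10 Mb is at 50.4% or more in LowK from day 52, in MidK1 from day 35 and in MidK2 from day 22 on, and lower in MEF1 (12.3%), MEF2 (3.47%), LowK day 35 (9.47%) and MidK2 day 18. The next 2 windows do not follow this in every library, with 3.90% at 20 to 30 Mb in LowK day 52 and 49.7% at 10 to 20 Mb in MidK2 day 18.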

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

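Among the tests below, those of other cells and of distance from Xist for the chromosome end, and both tests on mostly reference reads in the last libraries, were chosen only after the result was seen.

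At day 35 LowK and MidK1 stood on opposite sides of MEF1. The share of biallelic genes was 3.44 points below MEF1 in LowK (-3.44) and 11.8 points above it in MidK1, which drew attention because the single libraries of the 2 groups went opposite ways; this difference in direction was not tested between cultures. Between the 2 libraries themselves, 35 genes were biallelic in MidK1 alone and 0 in LowK alone (exact McNemar test, adjusted p = 1.86e-10 by Benjamini-Hochberg). At shared sites LowK was not parted from MEF1 (5 genes biallelic in LowK alone, 8 in MEF1 alone, exact McNemar test, adjusted p = 0.600 by Benjamini-Hochberg), while MidK1 was (25 and 5, adjusted p = 4.73e-04 by the same exact test).

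Insertions, deletions and other variants that the comparisons do not use were biallelic more often in MidK2 than in its control MEF2. Of such variants with at least 20 reads, 60.4% were biallelic at day 18, 66.7% at day 22, 61.7% at day 29 and 60.3% at day 36, against 50.5% (46.0 to 55.1) in MEF2. In the other set of tables MEF1 had 77.7% and the reprogrammed libraries 71.0 to 84.5%. Of single-nucleotide sites, only 14.9% were biallelic in MEF1 and 9.69% in MEF2. The shares of the other variants thus do not measure allele use alone, and what their difference reflects was not tested.

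Reference reads were more frequent in the first 30 Mb of the X chromosome, where Dynlt3, Tfe3, Hdac6, Uba1 and Timp1 lie. The tables argue against sequencing depth, since with sites thinned to 20 reads the first 10 Mb of MidK1 day 56 stayed 43.5 points (39.0 to 46.8) above the rest. Other cells that use the reference X chromosome stay open: housekeeping genes outside the first 30 Mb had median rises of 0.177 (-0.138 to 0.558) times that of all tested genes within it in LowK day 56, 0.189 (0.0478 to 0.324) in MidK1 day 56 and 0.0592 (0.00204 to 0.349) in MidK2 day 36, and these intervals are not all below the limit of 1 in 3. This test replaced one with called genes alone, which selection made void, and 2 that assumed equal rises of all genes: first 30 Mb minus rest, median reference shares differed by 5.16 points (0.818 to 10.5), 21.2 (11.3 to 38.6) and 14.7 (1.66 to 22.4), not all above a limit of 5, and biallelic genes by 27.6 points (13.5 to 42.0), 41.1 (26.6 to 52.7) and 39.1 (25.8 to 52.1). Distance from Xist stays open too, because at matched distances of 32.9 to 65.8 Mb few genes were called on either side (lowest Fisher's exact p = 0.514, 0 of 22 and 2 of 34 genes in LowK day 56), so early reactivation at this end remains a hypothesis.

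Among genes called higher than in the MEF library of their set, Bgn and 8 others had mostly reference reads in the last libraries. A few fibroblast-like cells that use the reference X chromosome could give this for genes that reprogrammed cells hardly transcribe, and for Bgn this explanation fits: its reference reads were at most 1.40 times those expected from the list of fibroblast-expressed genes, and 0.627 times in MidK2 day 36 (Bgn was left out of the list's median only after a first ratio was seen). For the other genes the tables argue against it at the share of such cells that the list gives. The lower quartile of observed over expected reference reads was 39.9 and the lowest 35.5 over 12 values of gene and library. These genes were picked for mostly reference reads, which raises the ratio, and Plp2 is itself on the list. Bgn in the last libraries is therefore not taken as evidence of reactivation in reprogrammed cells. LowK day 35 was outside this test, and there 75.2% of 218 Bgn reads were of the reference allele. The list gave an expectation of 0 there, but values below 0 were set to 0. The list's median change from MEF1 was -1.64 points, so a small share of such cells could not be seen. The expectation of 0 therefore decides nothing for LowK day 35.

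In MidK2 days 22 and 29 reference reads were also frequent in many windows outside the first 30 Mb, and fibroblast-expressed genes such as Tmsb4x and Maged2 were among the called genes. Depth is argued against, since with sites thinned to 20 reads biallelic genes were 46.5% and 41.2% on these days and 20.6 points or more above day 36, where they were 20.6%. Fibroblast-like cells with the reference X chromosome stay open: outside the first 30 Mb the reference share went with coverage in MEF2 over coverage in the library, with a rank correlation of 0.270 (0.0935 to 0.432) and 0.196 (0.0198 to 0.369) over genes that are not independent. The share of such cells taken from the fibroblast-expressed genes would give a median rise of 4.51 points there at day 22, against 7.17 observed, and at day 29 a rise close to the 4.82 observed. Less the reads expected from such cells, the called genes went from 18 to 11 on both days, from 20 to 18 at day 36, and stayed at 22 in MidK1 day 56 and 8 in LowK day 56.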

How the results depend on the processing

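Alternatives chosen only after the data were seen were the same caller limits in all libraries, genes with marker sites, the summed share, and those that leave out the first 30 Mb, MidK2 days 22 and 29, the fibroblast-expressed list or reads expected from fibroblast-like cells.

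Of 97 values of the main results under alternatives, some of them entered under 2 results, none reversed, 13 moved and 1 passed the threshold. For the tests within sets or courses and between LowK and MidK1 only the direction counts, since these designs could not give p under 0.05. Windows of 5 Mb left MidK2 day 36 at its main value of 51.0, after the first window of that setting was redefined on seeing the data, so they test nothing there. The difference in biallelic sites between MEF and reprogrammed libraries was 16.8 points (exact permutation p = 0.0909). It was 26.8 points (exact permutation p = 0.0758) without sites over 90% variant in every library that measured them, a setting that picks sites by their own values. With at least 50 reads per site it was 22.3 points (exact permutation p = 0.0455). At that coverage minimum called genes were 1 for LowK day 56, 9 for MidK1 day 56 and 10 for MidK2 day 36 against their MEF libraries, and 7, 8 and 12 between LowK and MidK1 at days 35, 52 and 56. The cause was fewer genes tested: of the main calls 2, 8, 10, 8, 9 and 12 were still tested, and 1, 8, 9, 7, 8 and 12 of these were called again. With no minimum difference the same comparisons gave 36, 64, 44, 82, 73 and 90 genes, because smaller differences then count. With at least 10 reads, the first 10 Mb of MidK2 day 36 lay 43.7 points above the rest instead of 51.0; the cause was not tested.

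The difference in biallelic genes between MEF and reprogrammed libraries stayed positive throughout, from 5.83 points with a window of 20 to 80% upward. It was 9.18 without the first 30 Mb and 11.6 to 17.8 with either MEF library left out. The difference between MidK1 and LowK was 10.6 points with the window of 20 to 80%, 10.8 without the first 30 Mb, 22.1 with at least 50 reads, and 14.3 to 16.0 with each day left out.

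Of 201 values of named genes, 195 kept their call and 6 became weaker, in Fundc1, Hdac6 and Wdr13 for LowK day 56, Tmsb4x for MidK2 day 36 and Zdhhc9 between LowK and MidK1 at day 52. The window of 20 to 80% does not enter the gene test and gave no value there, and the filter on quality and strands was possible only in the tables of MEF1, LowK and MidK1. Depth limits single sites, since the median site has 35 to 39 reads.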

Other observations

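Xist stayed on the reference allele in MidK2 while other genes gained reference reads. Its reference share was 93.7% (95% interval 90.6 to 95.8) at day 18, 93.8% at day 22, 93.9% at day 29 and 93.0% (90.2 to 95.1) at day 36, the last over 416 reads. Sites with the reference allele alone are not listed, so these shares are near the highest that can be seen. Rlim, which activates Xist, had a median minor share per site of 0 to 3.79% over all 12 libraries, which stays low also for sites that are almost all reference. Its summed reference share was 18.1% in MEF2 and 16.7 to 23.5% in MidK2, against 3.23 to 6.46% in the other set of tables.

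Kdm6a, a histone demethylase gene that escapes X inactivation, was measured in the 10 reprogrammed libraries and in neither MEF library, with reference shares of 42.2 to 72.4%. Ddx3x, biallelic in both MEF libraries, had reference shares of 54.6% (52.8 to 56.3) in LowK day 56, 54.1% (52.1 to 56.2) in MidK1 day 56 and 59.2% (57.6 to 60.8) in MidK2 day 36.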
